A study of Mus musculus with 8 samples.

How the data were processed

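Gene expression was measured by RNA sequencing in mouse OT-I CD8+ T cells, which carry a transgenic receptor for the ovalbumin peptide SIINFEKL. Per the labels, the T cells were sorted by flow cytometry after culture with peptide-pulsed bone marrow-derived dendritic cells lacking the liver X receptors (LXR), in the presence of vehicle (DMSO, control) or 2 uM RGX-104, a synthetic LXR agonist. Each group held 4 libraries, made from total RNA with an Illumina TruSeq kit per the labels' protocols.

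The authors deposited 1 table of whole-number read counts per gene, with no normalization. Per the submitters' processing notes, the tools named were cutadapt 2.10, STAR 2.7.5, R 4.1.0 and DESeq2 1.4, and the genome build was GRCm38. The counting step, its gene annotation and its strand setting are not given in the sources used here. Counts of overlapping genes and of gene families with near-identical members are therefore uncertain. Genes named below that overlap another gene include Srebf1, Itga4, Bcl2l11, Slc7a3, Tm7sf2, Mvd, Lss, Mcm7, Ung, Nr1h3, Il2ra, Gzma and Tcf7. The 4 control columns matched the numbered control samples. The 4 RGX-104 columns showed their group but not which sample each was, so RGX-104 replicates are numbered here by column. Every column of the table was used.

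Row names were matched to symbols of the RefSeq annotation of GRCm38, which gave the coordinates printed. Rows with a numbered suffix held copies of genes on alternate scaffolds. Among protein-coding genes, 1132 had such a copy and 26.9% of them passed the filter for testing, against 54.2% of the 20755 without one. Median mean counts were 0.125 and 27.3. Genes such as Tnf, Ltb, H2-Aa, H2-Ab1 and Rps18 had a copy and at most 4 counts in any library. A low count of a gene with a copy is therefore not read here as low expression. Protein-coding genes of the mitochondrial genome and most T cell receptor segments were not analysed here.

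Library totals ranged from 30642300 to 37714400 counts. Genes were kept by the edgeR function filterByExpr (minimum count 10, minimum total 15), which left 13290 of 41730 genes. The main test was the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with robust fitting, trimmed mean of M values (TMM) scaling, treatment as the only term, and Benjamini-Hochberg adjusted p under 0.05. Levels are in CPM, computed from the deposited counts with TMM-scaled library sizes. Standard errors (SE) of log2 fold changes were derived from the F statistic. Nothing in the labels says that the samples of a group came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

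Before the data were examined, 30 gene lists were fixed from textbook knowledge. The 27 lists with at least 3 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were alternatives. Genes were named by a rule fixed at the same time. It took the 10 largest changes in each direction among called genes of mean log2 CPM of at least 1 whose groups did not overlap, leaving out predicted gene models and receptor segments. It added up to 4 called members of each list with the largest changes, and a set of genes of the LXR pathway and of T cell activation whatever their result. Other members of a fixed list are named as examples, chosen after their values were seen. Some genes that the rule names are not reported here.

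On simulated counts for the RGX-104 comparison (13290 genes, 50 changed at each fold), edgeR recovered 30% of genes changed 1.1-fold, 82% changed 1.25-fold, 96% changed 1.5-fold and all changed 2-fold. Of its calls, 6.70% were false. The changed genes were drawn only from those of mean log2 CPM above 1, so recovery of lower genes was not tested. Camera called the simulated list shifted by 1.1-fold and 0 of the 27 fixed lists, which were not shifted as lists but could hold some changed genes. Those simulated genes varied independently and with the spread fitted for their level, so this did not test correlated genes or genes of unusual spread.

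Alternatives fixed in advance were DESeq2 1.42.0, limma-voom with sample weights, other scalings, other filters, 1 surrogate variable (sva 3.50.0), stricter thresholds and leaving out each library in turn. Corrections for GC content and transcript length, thinning to equal depth, leaving out genes with scaffold copies, and a block by column number were added after the data were seen. GC content and length came from the longest GENCODE transcript of each symbol and covered 92.4% of the tested genes.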

Results

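RNA sequencing counts were obtained from 8 libraries of sorted OT-I CD8+ T cells, 4 from cultures with vehicle and 4 from cultures with the LXR agonist RGX-104. The dendritic cells that presented the peptide lacked LXR, whereas the sequenced cells were the T cells. Control libraries held a mean of 35694000 ± 1668470 counts and RGX-104 libraries 32496300 ± 1956600 (SD, n = 4 each; two-sided exact permutation p = 0.0857). Chi-square per degree of freedom between libraries of a group was 1.36 for RGX-104 replicates 2 and 3 and 2.35 for RGX-104 replicates 1 and 4. For the other pairs it was 2.56 to 6.85. No pair agreed within counting noise, so none was merged, but repeat preparations of 1 RNA would exceed counting noise too, and the values do not show that the samples were separate cultures. The first principal component held 30.7% of the variance and separated the groups, with control replicate 4 at its control end.

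The comparison asked which T cell transcripts differed when the agonist was present in cultures whose dendritic cells lacked the receptor. Abca1, a cholesterol efflux transporter, rose from 1.72 ± 0.295 to 125 ± 6.21 CPM (SD, n = 4), a log2 change of 6.19 ± 0.07 (SE). Abcg1, a related transporter, rose from 43.3 ± 1.4 to 159 ± 2.96 CPM. Ifng, encoding interferon gamma, rose from 33.8 ± 3.62 to 76.4 ± 14.2 CPM, while interferon-inducible genes such as Gbp2 and Irf1 fell. Ifng was at 89.0 and 88.3 CPM in RGX-104 replicates 1 and 4 but at 64.2 and 64.0 CPM in replicates 2 and 3. Whether the libraries of these pairs were related was not tested. The transcriptional repressor Hic1 fell from 69.2 ± 1.46 to 22.3 ± 0.680 CPM. In all of these genes the 4 RGX-104 libraries lay on 1 side of the 4 control libraries. For Hic1 this was a condition of being named, and Gbp2 and Irf1 were chosen after their values were seen.

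With edgeR, 640 genes were higher and 549 lower with RGX-104 at adjusted p under 0.05, together 8.95% of the 13290 tested. Most changes were small, with a median of 1.14-fold among called genes, and 31 genes rose and 16 fell by at least 2-fold. Groups did not overlap in 14.5% of tested genes, where chance gives 2.86%. Against a fold of 1.2, 65 genes were higher and 45 lower, and with 1 surrogate variable 425 were higher and 365 lower. Without 1 of the closest pair of libraries, RGX-104 replicates 2 and 3, 479 genes were higher and 378 lower (without replicate 2) or 462 and 403 (without replicate 3).

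**Figure D1:**
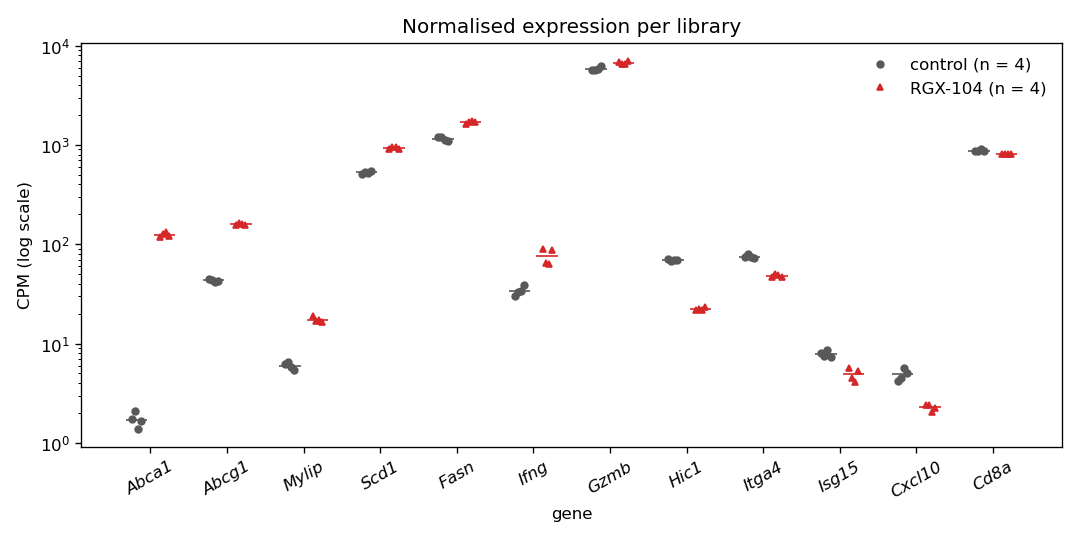
CPM on a log axis for 12 named genes, with 1 point per library, grey circles for control and red triangles for RGX-104 (n = 4 each), and a line at each group mean. Abca1 shows the widest gap between the groups of the genes drawn, from a mean of 1.72 to 125 CPM, and Gzmb has the highest level, with a mean of 5838 CPM in control libraries.

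LXR target genes rose as a group. Of 16 tested members 10 were higher and 0 lower, both over all genes and adjusted over the list alone, with a median log2 change of 0.49 (camera adjusted p = 4.89e-197 and adjusted p = 1.04e-05 with an estimated correlation). Abca1 lies on chromosome 4 from 53030789 to 53159988 (GRCm38), and its change had an edgeR adjusted p of 1.16e-27. Lexis1, a noncoding RNA gene of the same chromosome from 53204930 to 53218681, rose by 5.99 ± 0.23 (log2, SE) from 0.0702 CPM. Mylip, encoding a ubiquitin ligase, rose by 1.54 ± 0.07 and Arl4c by 1.11 ± 0.04. Apoe, Pltp, Smpdl3a and Abcg4 did not pass the test. The receptors themselves did not pass either, with Nr1h2 at 88.2 and 83.8 CPM and Nr1h3 at 0.804 and 0.699 CPM in control and RGX-104 libraries (edgeR adjusted p = 0.126 and 0.613).

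Fatty acid synthesis genes rose, with 13 of 18 tested members higher and 0 lower, and 14 higher when adjusted over the list alone. The median log2 change was 0.28 (camera adjusted p = 9.71e-61 and adjusted p = 5.62e-04 with an estimated correlation). Scd1, a fatty acid desaturase, rose by 0.82 ± 0.03 (SE) to 935 CPM, the lipogenic regulator Srebf1 by 0.77 ± 0.03 to 527 CPM, and fatty acid synthase Fasn by 0.56 ± 0.03 to 1695 CPM. This list shares 6 genes with the LXR list, and of its 12 tested members off that list 7 were higher, Acsl3 and Lpin1 among them. Acsl3 overlaps Utp14b and has a scaffold copy.

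Cholesterol biosynthesis genes moved less. Of 25 members 9 were higher and 1 lower, and adjusted over the list alone 12 were higher and 2 lower, with a median of 0.07 (camera adjusted p = 3.71e-05, but adjusted p = 0.164 with an estimated correlation). Tm7sf2 rose by 0.34 ± 0.05, Mvd by 0.25 ± 0.04 and Lss by 0.25 ± 0.03 (log2, SE).

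Interferon response genes fell. Of 33 tested members 19 were lower and 0 higher, and 21 were lower when adjusted over the list alone, with a median log2 change of -0.31 (camera adjusted p = 4.89e-25 and adjusted p = 5.62e-04 with an estimated correlation). Cxcl10, a chemokine, fell from 4.89 ± 0.635 to 2.28 ± 0.177 CPM, and Isg15 from 7.90 ± 0.535 to 4.93 ± 0.711 CPM (SD, n = 4). Gbp2 changed by -0.60 ± 0.03 and Iigp1 by -0.66 ± 0.06 (log2, SE), both of families with similar members between which reads can be shared. The transcription factor gene Irf1 (-0.34 ± 0.03) also fell. Stat2, Irf9 and Socs1 did not pass the test.

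Effector and cytotoxic genes moved both ways, with 7 of 24 higher and 6 lower, over all genes and adjusted over the list alone (camera adjusted p = 0.787). Ifng rose by 1.17 ± 0.16 (log2, SE; edgeR adjusted p = 0.00632), granzyme gene Gzmb by 0.20 ± 0.03 and perforin gene Prf1 by 0.16 ± 0.04. Tbx21, a regulator of effector fate, changed by -0.27 ± 0.03, Prdm1 by -0.37 ± 0.06 and Il12rb2 by -0.25 ± 0.03. Genes of the cytokine list, which also holds helper-type genes that encode no cytokine, were higher in 7 and lower in 1 of 18. Adjusted over the list alone 8 were higher and 1 lower. Il3 and Gata3 were among those higher (camera adjusted p = 0.00977, but adjusted p = 0.234 with an estimated correlation). Tnf had 0 counts in every library and Il2 between 1 and 17, and both have scaffold copies, so their expression was not assessed.

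Activation genes were higher in 8 and lower in 3 of 28, with 9 and 3 adjusted over the list alone (camera adjusted p = 0.151). Irf8 changed by -0.29 ± 0.03 and Myc by -0.24 ± 0.04, whereas the costimulatory gene Cd40lg rose by 0.41 ± 0.09. Cd69, Il2ra and Cd44 did not pass (edgeR adjusted p = 0.732, 0.223 and 0.693). Naive and memory genes were higher in 2 and lower in 2 of 19 (camera adjusted p = 0.729), with Tcf7 at 377 and 375 CPM (edgeR adjusted p = 0.896). Inhibitory receptor genes were higher in 3 and lower in 3 of 18 (camera adjusted p = 0.787), and Pdcd1 did not pass (edgeR adjusted p = 0.567). CD8 T cell identity genes were higher in 2 and lower in 4 of 11 (camera adjusted p = 0.287), and Cd8a fell by 7.73%.

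Trafficking genes were higher in 7 and lower in 5 of 23 (camera adjusted p = 0.778), with a median of 0.06 and a mean of -0.03. Fut7, a fucosyltransferase gene, rose by 1.27 ± 0.10. The gut-homing receptor gene Ccr9 fell from 0.864 ± 0.148 to 0.214 ± 0.0705 CPM, and the integrin gene Itga4 fell from 75.2 ± 3.71 to 48.1 ± 1.38 CPM (SD, n = 4). Other large changes lay outside the lists. Lgals3 (1.24 ± 0.07), Sema4a (1.19 ± 0.05), Pnpla3 (1.27 ± 0.11) and Endou (1.26 ± 0.13) rose. Enpp5 (-1.17 ± 0.13), Serpina3f (-1.03 ± 0.12), Serpina3g (-0.92 ± 0.08), Asb2 (-0.84 ± 0.05), Enpp4 (-0.80 ± 0.05), Utf1 (-0.79 ± 0.10) and Tgm2 (-0.76 ± 0.09) fell. Hic1 overlaps Smg6, and the Serpina3 genes are close paralogs.

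Amino acid response genes were lower in 8 and higher in 0 of 30, with Asns (-0.38 ± 0.03) and Slc7a3 (-0.44 ± 0.05) among them, and lower in 13 and higher in 3 adjusted over the list alone (camera adjusted p = 6.62e-05, but adjusted p = 0.289 with an estimated correlation). S phase genes were lower in 7 and higher in 1 of 29, in which Mcm2 fell by 7.01% and Mcm7 fell by 7.14%, and lower in 12 adjusted over the list alone (camera adjusted p = 0.00977, but adjusted p = 0.501 with an estimated correlation). Of 29 mitosis genes 0 passed with edgeR, DESeq2 or limma-voom and 5 had an unadjusted p under 0.05 (camera adjusted p = 0.577), and Mki67 was at 1088 and 1177 CPM (edgeR adjusted p = 0.189). Ribosome biogenesis genes were higher in 1 and lower in 1 of 34 (camera adjusted p = 0.0383, but adjusted p = 0.849 with an estimated correlation).

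Glycolysis (3 higher and 2 lower of 30), apoptosis (7 and 2 of 23), immediate early (1 and 4 of 17), histone (1 and 0 of 13) and cytosolic ribosomal protein genes (0 and 2 of 35) were not called as lists in the main test (camera adjusted p = 0.747, 0.144, 0.0638, 0.893 and 0.0759). The immediate early list was called lower with DESeq2, limma-voom and no filter (camera adjusted p = 0.0390, 0.0134 and 0.0184), as was the cytosolic ribosomal list (0.0168, 0.00474 and 0.0154). With an estimated correlation neither was called (adjusted p = 0.849 and 0.883). Each list's p was also compared over the 35 splits of the libraries, a check added after the data were seen. Many of these splits still carried part of the treatment contrast, so the check is not a clean measure of chance. In that check 14 and 17 splits, the real one included, gave a p as small as the main test. The apoptosis list was called higher with limma-voom (0.0381) and by fry (0.000914), which does not compare a list with other genes, but not with an estimated correlation (adjusted p = 0.289). Bcl2l11, a pro-apoptotic gene, changed by -0.43 ± 0.05. Oxidative phosphorylation and unfolded protein response lists had 0 members called by edgeR of 31 and 25 tested (camera adjusted p = 0.0654 and 0.423). At an unadjusted p under 0.05 they had 5 and 6, and DESeq2 and limma-voom each called 0 and 1. As a list, oxidative phosphorylation was called lower with DESeq2, limma-voom and no filter (camera adjusted p = 0.0363, 0.00885 and 0.0115), but not with an estimated correlation (adjusted p = 0.849), and 15 of the 35 splits gave a p as small as the main test.

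Markers of other cells that the sort could hold differed in level. Lyz2, Csf1r, Spi1, Tyrobp and Fcer1g, abundant in myeloid cells and without scaffold copies, had at most 13 counts in any library. Dendritic cell markers were higher in 3 and lower in 0 of 13, and in 5 and 0 adjusted over the list alone (camera adjusted p = 2.49e-04, but adjusted p = 0.196 with an estimated correlation). Ccl22 rose from 2.05 to 4.83 CPM and Cd74 from 26.5 to 33.2 CPM, while Itgax did not pass (edgeR adjusted p = 0.554). Cst3 was at 48.1 and 48.8 CPM and Batf3 at 37.9 and 39.1 CPM, and neither passed. The tested markers summed to 205 CPM in control and 227 CPM in RGX-104 libraries. The 5 myeloid transcripts above summed to at most 0.649 CPM in a control and 0.744 CPM in an RGX-104 library. The marker sums are therefore not read here as RNA of dendritic cells. Macrophage markers were higher in 1 of 4, Ctss (camera adjusted p = 0.0524, but 0.0480 with DESeq2, 0.0142 by fry and adjusted p = 0.289 with an estimated correlation), and the CD4 and regulatory T cell list was higher in 2 and lower in 2 of 8 (camera adjusted p = 0.878), with summed levels of 1127 and 1183 CPM. Cd4 itself, without a scaffold copy, had 3 to 14 counts per library, so these sums are not read here as CD4 T cells. NK cell markers were higher in 1 and lower in 2 of 5, with a median of 0.11 against a test in the lower direction (camera adjusted p = 0.547). Erythroid markers had 0 called of 3 and B cell markers 0 of 2 by edgeR, DESeq2 or limma-voom, with 0 at an unadjusted p under 0.05, and 0 neutrophil markers were tested.

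**Figure D2:**
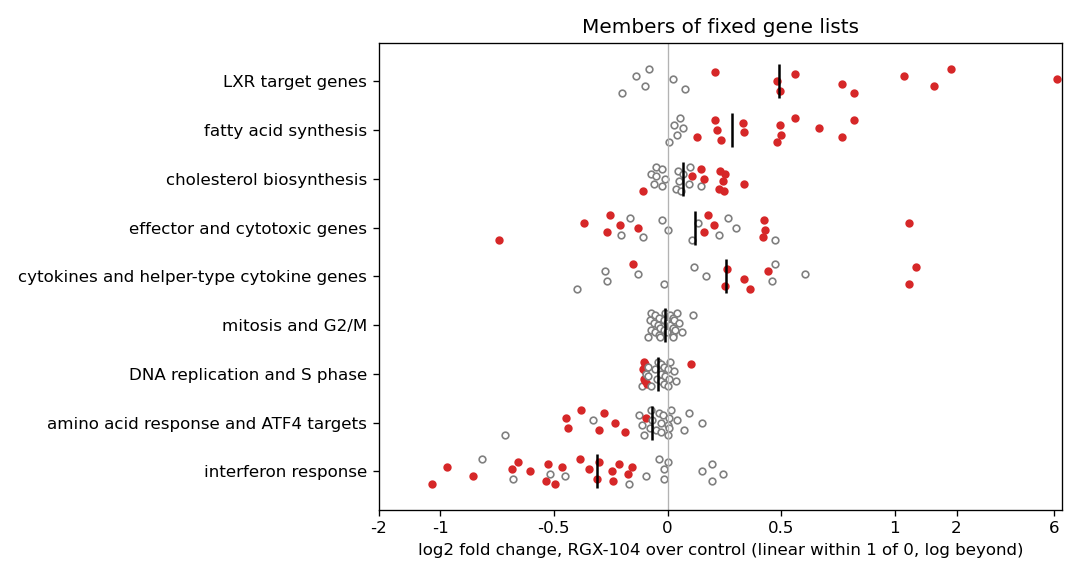
Log2 fold changes of tested members in 9 fixed gene lists, with 1 point per gene, filled red where edgeR adjusted p was under 0.05, and a black line at each list's median. The axis is linear within 1 of 0 and logarithmic beyond. LXR target genes (median 0.49) and fatty acid synthesis genes (median 0.28) lie mostly right of 0 and interferon response genes (median -0.31) mostly left.

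At the preset correlation camera called 5 lists higher and 4 lower. Only the LXR, fatty acid synthesis and interferon lists kept their call with an estimated correlation. Other groupings of the same 8 libraries gave up to 14 lists at the preset value. The highest counts came from groupings that kept most libraries of a treatment together and so still carried part of the treatment contrast. Among groupings that mixed the treatments evenly the highest gave 9 and the others fewer, so the count of 9 lists is not told apart from chance.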

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

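The tests in this part on GC content, depth, paralogs and myeloid RNA were chosen after the results were seen. The counts of genes and of lists over splits of the libraries were set before. The comparison of each list's own p over the splits was added after the list count was seen. In 214 groups of 4 libraries checked, 5 held a value far from the other 3, where chance would give about 10.7 in unselected groups. Most of these groups were of named genes, many named for a call that a stray value would weaken. The low number therefore does not show that the libraries were free of stray values. Enpp4 was at 64.2 CPM in control replicate 4 against 55.8 to 56.4 in the others, and Ung at 70.1 CPM against 66.8 to 67.3. Utf1 was at 4.70 CPM in control replicate 1 against 5.49 to 5.55, and Rps14 at 898 CPM in control replicate 2 against 933 to 940. Gzma was at 2.69 CPM in RGX-104 replicate 1 against 4.61 to 4.84.

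Many small changes were called. Of the 35 splits of the 8 libraries only 1, the real grouping, gave as many genes higher (640) or lower (549). The highest of the others gave 5, so a chance division of these libraries is unlikely for both counts. It is not excluded, since 1 in 35 is the smallest share that these splits can give. Splits of libraries also cannot address a chance difference between the cultures they came from. After a correction for GC content 98.1% of the called genes stayed called, and after thinning to the smallest library 90.2% did, with 0 changes of sign, which argues against either as the whole cause. A response of the T cells to the agonist remains a candidate explanation, although a handling difference between the groups was not tested.

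The count of shifted lists behaved otherwise. In 12 of the 35 splits, the real one included, camera at the preset correlation called at least 9 lists, and the highest other split called 14. That split set control replicates 1, 2 and 4 with RGX-104 replicate 1, so it still carried part of the treatment contrast. Most other splits with at least 9 lists did too. An evenly mixed split, control replicates 1 and 2 with RGX-104 replicates 1 and 2, also called 9, so chance is not excluded for that count. With an estimated correlation, a count added after this was seen, the real grouping gave 3 lists and the highest other split 0. The LXR, fatty acid, cholesterol and interferon lists each had their smallest p in the real grouping. A p as small arose in 3 splits for the amino acid list, 4 for dendritic cell markers, 5 for cytokines, 7 for S phase and 22 for ribosome biogenesis, the real one included. Splits that kept most libraries of a treatment together can give a small p for a list that responds to RGX-104. These ranks therefore do not decide between chance and a response for these lists.

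Interferon response genes were lower although Ifng was higher. Reads shared between paralogs would leave members outside such families unshifted, but their median was -0.24 (95% bootstrap interval -0.49 to -0.02, 17 genes). The 5 myeloid transcripts Lyz2, Fcer1g, Tyrobp, Csf1r and Spi1 summed to at most 0.649 CPM in a control library, against a summed fall of 462 CPM in the list, which argues against RNA of myeloid cells in the controls. The list's median after the GC correction was -0.31. No biological explanation of the pattern was tested.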

How the results depend on the processing

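The corrections for GC content and length, thinning, removal of genes with scaffold copies and the column block were chosen after the data were seen. The counts of 640 higher and 549 lower genes stayed within 1.5 times under DESeq2, limma-voom, the other scalings and both filters. With 1 surrogate variable they were 425 and 365, at adjusted p under 0.01 they were 344 and 280, and against a fold of 1.2 they were 65 and 45. The last 2 are stricter by construction. The surrogate variable ran from -0.29 to 0.72 in control and from -0.42 to 0.11 in RGX-104 libraries, and rose with column number in both groups. Why the counts fell with it was not tested. Of the 9 lists called, 3 kept their call with an estimated correlation. With at least 10 CPM in 4 libraries 6 lists were called. The S phase (adjusted p = 0.0522), ribosome biogenesis (0.155), cytokine (0.0522) and dendritic cell (0.0505) lists lost their calls and the macrophage list gained one (0.0290). With 1 surrogate variable the S phase (0.0850) and ribosome biogenesis (0.595) lists lost theirs and T cell activation gained one (0.00705), all by camera of limma. Upper quartile scaling (0.0670) and library size alone (0.0621) ended the ribosome biogenesis call. DESeq2 called 13 lists, limma-voom 13 and no filter 12. In each the oxidative phosphorylation, cytosolic ribosomal and immediate early lists were called lower, and DESeq2 added macrophage markers and limma-voom apoptosis. Fry called 10 lists, adding apoptosis and macrophage markers and losing ribosome biogenesis (0.391). Length correction (0.0371) and leaving out genes with scaffold copies (0.0479) added macrophage markers, the latter also the immediate early list (0.0168). Leaving out 1 library gave 462 to 719 genes higher, 377 to 621 lower and 8 to 12 lists. No called gene changed sign, and 0 named genes or lists reversed, under any alternative. Of 92 called named genes, 14 lost their call in at least 1 leave-one-out fit (adjusted p up to 0.144, edgeR) and 15 under another alternative. The ribosome biogenesis list lost its call without control replicates 1 (0.0555) or 4 (0.390) and without RGX-104 replicates 2 (0.148) or 3 (0.113). Without control replicates 1 or 2 or RGX-104 replicate 4, the oxidative phosphorylation (0.0367, 0.0161 and 0.0293) and immediate early lists (0.0164, 0.0322 and 0.0157) gained calls, and without the last 2 of these the cytosolic ribosomal list did (0.00807 and 0.0341).

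The labels do not pair the samples. Same-numbered columns deviated together with correlations of 0.14, 0.07, 0.04 and 0.16, and every library but control replicate 3 correlated best with its own number, a hint from the data and not the design. With column number as a replicate block 1109 genes were higher and 906 lower.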

Other observations

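The genes in this part were chosen after their values were seen, except that the test on unseen retinoic acid genes and its GC check were set before their results. Klrc1, a lectin-like receptor gene, rose from 4.07 to 8.85 CPM (log2 change 1.13 ± 0.12, SE) and the interleukin receptor gene Il18r1 rose from 3.32 to 6.18 CPM (0.90 ± 0.10). Both interferon gamma receptor genes fell, Ifngr1 by 0.42 and Ifngr2 by 0.31 on the log2 scale. Among nuclear receptor genes, Rxra rose by 0.82 ± 0.05 and Rara by 0.59 ± 0.04, and the retinoic acid binding protein gene Crabp2 rose by 0.99 ± 0.05. The Klrc genes are close paralogs between which reads can be shared.

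Of 6 genes known to be induced by retinoic acid that were picked after their values were seen, Ccr9, Itga4, Hic1, Asb2 and Tgm2 were lower and Itgb7 did not pass (-0.07 ± 0.04, log2, SE; edgeR adjusted p = 0.344). Crabp2, which retinoic acid also induces and whose rise had been seen, was not among the 6, so the pattern rests in part on that choice. Lower retinoic acid signalling may account for this as a hypothesis. Of 9 further such genes whose values had not been seen, 4 were tested, and their mean log2 difference was -0.27 ± 0.08 (SE), with a camera p of 0.483. Stra6 fell (-1.27 ± 0.26), Rarg rose (0.25 ± 0.07), and Rarb and Cd38 did not pass, so these genes left the hypothesis undecided. The median of the 10 tested genes was -0.70 before and -0.71 after the GC correction, which argues against GC content.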
